A study of Homo sapiens with 6 samples.

How the data were processed

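RNA from MCF7 cells carrying the empty vector (Neo) or the PAR4 cDNA, untreated or after 24 h with 100 nM docetaxel, was hybridised to 6 two-colour Agilent arrays. Per the labels, the cells were kept in 10% serum with 800 µg/ml G418, 162 ng of RNA was labelled per sample with Cy5, and a universal human reference RNA from 10 cell lines was labelled with Cy3. Whether the untreated cells received a vehicle is not given in the sources used here. The arrays lay on 2 slides. Slide 1 held untreated Neo cells, replicate 2 of docetaxel-treated Neo cells and replicate 2 of docetaxel-treated PAR4 cells. Slide 2 held untreated PAR4 cells and replicate 1 of both docetaxel groups. Untreated samples had position 1 on their slide, docetaxel-treated Neo samples position 2 and docetaxel-treated PAR4 samples position 3, so that position goes with treatment in both lines and, after docetaxel, with the line as well.

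The authors scanned the arrays with Agilent Feature Extraction 11.5.1.1 (array design 026652, probe coordinates on hg19). Per the file headers, each scanner file holds the raw median signal and local background of both channels as an intensity for 44495 features, of which 43118 spots carry 34127 gene probes. Per the file headers, the same files hold processed signals, also an intensity, which are background-subtracted, spatially detrended and dye-normalised. Their log ratio is a log10 of processed Cy5 over processed Cy3 per the file headers, and was checked against the processed signals (largest difference 4.01e-07). The table of values as deposited is best described as a score. It equals that log10 ratio times 1e+09, within a relative tolerance of 0.005, for 44495 of 44495 features on every array. The medians of its columns were 0 except for replicate 2 of docetaxel-treated Neo cells, at 0.00629 on the log10 scale. The flags of the scanner files are 0 or 1 (other), as deposited. No column with values per sample was left unused.

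The fit started from the raw signals. Background was corrected with normexp (offset 50) on median foreground and median local background, and log2 ratios of Cy5 over Cy3 were normalised by loess within each array, with control and flagged spots given no weight. Flagged spots were left out, and the spots of a probe were averaged. Probes were tested when Cy5 was well above background on at least 2 of the 6 arrays, which kept 26267 probes, and the brightest tested probe stood for its gene, giving 20496 genes. Names came from the accessions in the array files for 25771 probes and from the file's own symbol where that is a current symbol for 2207. For 6149 probes only the file's name was at hand, and 3382 names were replaced by a current symbol. The gene table paired accessions with symbols and was used for names only.

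Differences were tested with limma 3.58.1 in R 4.3.3 with 1 mean per group over all 6 arrays (2 residual degrees of freedom, prior degrees of freedom 3.06, prior SD 0.131). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and tests were two-sided. The 6 comparisons were docetaxel against untreated as the mean of both lines, the same in Neo and in PAR4 cells, the difference between those changes, and PAR4 against Neo cells after docetaxel and without treatment. Tables were read with the R packages data.table (version 1.17.8) and jsonlite (version 2.0.0), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

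Gene lists were tested with camera in limma, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 25 lists within a comparison. With an estimated correlation camera relies on the 2 residual degrees of freedom of the fit, so that a list could hardly be called whatever its correlation. Estimates above the preset included mesenchymal (0.385), luminal (0.383), ribosomal (0.37), estrogen-response (0.183) and interferon genes (0.102). For such lists the preset p-values are likely too small, so the loss of their calls is not only a matter of degrees of freedom. Estimates below the preset included mitosis (-0.0126), tubulins (-0.036) and immediate early genes (-0.0354). Lists needed at least 5 measured members. Camera used the 20184 genes measured on all 6 arrays, whereas medians and counts used every measured member. Members were also adjusted over the list alone. The lists were mitosis and G2/M, DNA replication, histones, p53 targets, apoptosis regulators, partners of PAWR, tubulins, microtubule-associated proteins, estrogen response, drug transport and metabolism, NF-kB and cytokines, interferon response, immediate early genes, integrated stress and unfolded protein response, heat shock, cholesterol synthesis, hypoxia and glycolysis, autophagy and lysosome, luminal epithelial, basal epithelial, mesenchymal, leukocytes, endothelium, ribosomal proteins and reference genes. RPLP0, XBP1, STC2, IER3, ESR1 and several other genes belong to more than 1 list. The list of partners of PAWR holds PAWR itself.

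The comparisons, lists, tests, thresholds, most alternatives and the rule for naming genes were fixed before the data were examined. By that rule PAWR and F2RL3 were named first. Then came, per comparison, the 10 genes with the largest rise and the 10 with the largest fall that passed and whose arrays did not overlap between the sides. Where fewer than 3 passed in a direction, those and the genes of smallest p up to 3 were given as values that did not pass. From each list described, up to 4 members of smallest p were named, together with members opposing the list's direction. After the values were seen, the last part was narrowed to opposing members that passed over the list alone, a few lists were given by their median only, and XIST and Y-linked genes were not considered for naming. ALB, TYR and HBG1 as markers of the reference RNA were chosen after their values were seen.

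The procedure was tested on simulated data with known changes in 200 of 20184 genes. Alternatives planned beforehand concerned background correction, Agilent's processed signals, normalisation, the Cy5 channel alone, the deposited values, the filter on dim probes, the choice of probe, slide or replicate number as a block, the variance model, a 2-fold minimum, an additive model, fits without 1 array each, and values within a slide. Median centring stands for the alternative without loess. Removal of ratio compression and removal of a trend with probe GC content, both by loess per array, were added after the data were seen.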

Results

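Gene expression was profiled in MCF7 cells, an estrogen receptor-positive line from a breast adenocarcinoma. The cells had been stably transfected with a plasmid carrying the full-length PAR4 cDNA (PAR4 cells) or with the empty vector (Neo cells). Each line was sampled without treatment and after 24 h with 100 nM docetaxel, a taxane that stabilises microtubules and blocks cells in mitosis. The series held 6 two-colour arrays in 4 groups. These were 1 array of untreated Neo cells, 2 of docetaxel-treated Neo cells, 1 of untreated PAR4 cells and 2 of docetaxel-treated PAR4 cells. The labels call the samples biological replicates, and the limma p-values measure only the spread between these samples. P-values of the preset camera test set the genes of a list against the other genes. They rest on the spread between genes under an assumed correlation of 0.01, not on the spread between arrays. On every array the sample carried Cy5 and a pooled RNA from 10 human cell lines carried Cy3, with no dye swap. Each value is therefore a log2 ratio of sample to reference. The median Cy5 signal per array lay between 92.5 and 195 units, and 72.3% to 78.1% of the gene spots were well above background in Cy5. The number of arrays limits the precision. Neither untreated group has a replicate of its own, and their spread was assumed to equal that between the replicates of the docetaxel groups.

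The transfected gene was examined first. PAWR, which encodes the pro-apoptotic protein PAR4 (prostate apoptosis response 4), was measured with a 60-base probe on chromosome 12 from 79990360 to 79990419 (hg19), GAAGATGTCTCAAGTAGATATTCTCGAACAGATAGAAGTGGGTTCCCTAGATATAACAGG. Its log2 ratio was -0.65 in untreated Neo cells and -0.51 and -0.52 in docetaxel-treated Neo cells. In PAR4 cells it was 1.14 without treatment and 0.80 and 0.82 after docetaxel. After docetaxel, the normalised ratio of PAWR was 2.51-fold higher in PAR4 than in Neo cells (log2 difference 1.33, SE 0.10, 2 arrays against 2, limma adjusted p = 0.0303). With slide as a block no gene passed in this comparison, PAWR included. Raw Cy5 signals, not scaled between arrays, lay further apart, at 2784.5 and 2007 units in docetaxel-treated Neo and 19517.5 and 8178.5 in docetaxel-treated PAR4 cells. In untreated cells the PAWR log2 difference was 1.80 (SE 0.14, 1 array against 1, limma adjusted p = 0.413), which did not pass over all genes. F2RL3, a thrombin receptor gene that is also called PAR4, had log2 ratios between 0.09 and 0.45 on the 6 arrays. Its difference of -0.26 between PAR4 and Neo cells after docetaxel did not pass (SE 0.11, limma adjusted p = 0.205). The log2 change of PAWR itself after docetaxel was -0.10 over both lines (SE 0.09).

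**Figure D1:**
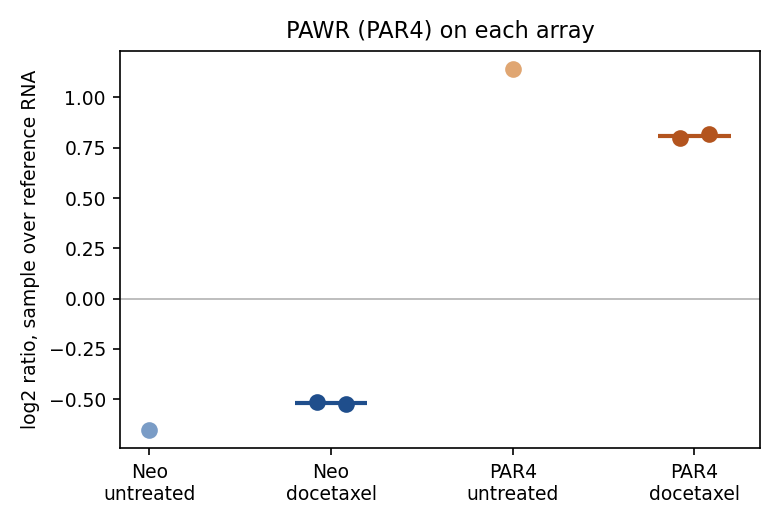
Log2 ratio of PAWR over the reference RNA (y axis) on each of the 6 arrays, by group (x axis); points are arrays and horizontal bars the means of the groups with 2 arrays. The 3 Neo arrays lie between -0.65 and -0.51 and the 3 PAR4 arrays between 0.80 and 1.14.

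The first comparison asked what docetaxel does to both lines, taken as the mean of the changes within Neo and within PAR4 cells. No gene passed over all genes tested, but genes of mitosis and tubulin genes stood higher after docetaxel as groups by limma's camera with a preset inter-gene correlation. Neither group was called otherwise (adjusted p = 0.332 with an estimated correlation). With 2 residual degrees of freedom that second test could hardly call any list. The loss of a call thus decides little for mitosis and tubulin genes, whose estimated correlations lay below the preset. Of 31 genes of mitosis and the G2/M phase, 26 lay above 0, with a median log2 change of 0.39. Adjusted over the list alone, 19 of them were higher and 2 lower. The leading members were CDC20, an activator of the anaphase-promoting complex (1.15, SE 0.10), and CCNB1, which encodes cyclin B1 (1.00, SE 0.09). They were followed by PLK1, a mitotic kinase (0.81, SE 0.10), and the survivin gene BIRC5 (0.75, SE 0.09). TOP2A (-0.35, SE 0.11) and CDK1 (-0.34, SE 0.09) were lower over the list alone. CDK1 read 0.07 with median centring, where the median of all genes was 0.112, and 0.20 with ratio compression removed. Of 17 measured tubulin genes, 13 were higher and 1 lower adjusted over the list alone (median 0.52). Among them were TUBA1C (0.80, SE 0.10), TUBB (0.78, SE 0.10) and TUBB3 (0.69, SE 0.09), while TUBB2B was lower (-0.999, SE 0.20). The main probe of TUBB8 gave 1.14 (SE 0.12) and another of its probes -0.19.

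Interferon-induced genes also stood higher after docetaxel, with a median log2 change of 0.44 over 33 genes, 12 of them higher and 1 lower over the list alone and 0 over all genes by limma. The interferon list was called by the preset camera test only (adjusted p = 0.503 with an estimated correlation). OAS3 was higher by 0.83 (SE 0.13), USP18 by 0.88 (SE 0.16), OAS1 by 0.86 (SE 0.16) and RIGI, a cytosolic RNA sensor, by 0.60 (SE 0.12). MX2 read -0.47 (SE 0.10), and its other probe 0.35. Immediate early genes, which respond within minutes to growth signals, stood lower (median -0.28 over 25 genes, 8 lower and 1 higher over the list alone), by the preset test only (adjusted p = 0.34 with an estimated correlation). They were led by EGR1 at -0.85 (SE 0.09), MYC at -0.73 (SE 0.11), FOS at -0.65 (SE 0.10) and EGR2 at -0.61 (SE 0.10), and KLF4 read 0.37 (SE 0.09). Genes of hypoxia and glycolysis stood lower too (median -0.28 over 23 genes, 6 lower over the list alone), by the preset test only (adjusted p = 0.507 with an estimated correlation). With median centring their median was 0.08, below that of all genes at 0.112, and the list was not called. The hypoxia genes were led by ADM, which encodes adrenomedullin (-1.19, SE 0.13), LDHA (-0.97, SE 0.19), NDRG1 (-0.85, SE 0.17) and HK2 (-0.57, SE 0.10). In Neo cells alone the medians were -0.03 for immediate early and -0.06 for hypoxia genes, against -0.66 and -0.40 in PAR4 cells. The lower values of these lists in the mean of both lines thus came mostly from PAR4 cells.

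By the preset camera test the adjusted p was 3.15e-08 for mitosis and 3.04e-07 for tubulins (both adjusted p = 0.332 with an estimated correlation). It was 1.41e-06 for interferon, 0.000101 for immediate early and 0.00102 for hypoxia genes (adjusted p from 0.34 to 0.507 with an estimated correlation). Luminal epithelial genes had a median of 0.43 (adjusted p = 0.00566), which was 0.03, with camera pointing the other way, in the Cy5 channel alone. Mesenchymal genes had a median of -0.46 (adjusted p = 0.00174). Both lists had adjusted p = 0.605 with an estimated correlation. Genes of DNA replication had a median of -0.19 that turned to 0.17 with median centring (adjusted p = 0.0114, and adjusted p = 0.498 with an estimated correlation). With ratio compression removed the medians were 0.51 for mitosis, 0.63 for tubulins, 0.19 for interferon and -0.21 for immediate early genes. Those of hypoxia (-0.10), luminal (0.10), mesenchymal (-0.06) and replication genes (-0.03) were then no longer called.

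Over all 20202 genes tested for the mean of both lines, limma called 0 genes, with a smallest adjusted p of 0.053, while 4719 genes had an unadjusted p under 0.05. On the higher side the genes of smallest p were PIMREG (log2 change 1.09, SE 0.09), CDC20 and CCNB1, each with an adjusted p of 0.0827. On the lower side PMF1 had an adjusted p of 0.053 (-2.35, SE 0.10), but it rests on 1 spot of the untreated Neo array with a raised local background and read 0.27 without background subtraction. The translation factor gene EIF4A2 (-1.25, SE 0.09) and ALB (-2.64, SE 0.21) had an adjusted p of 0.0827. The count was 2813 without background subtraction, 2435 in the Cy5 channel alone, 957 or 2903 without the first or second PAR4 docetaxel array, and 0 with slide as a block. In simulated data of this design with 200 of 20184 genes changed, 49.5% of changes of 1 on the log2 scale and 96% of changes of 2 were recovered for this comparison. The recovered share depends on how many genes change, so it need not hold for these data.

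In Neo cells alone, docetaxel was followed by higher levels of mitotic genes as a group by the preset camera test, though not otherwise (adjusted p = 0.222 with an estimated correlation). All but 2 of the 31 mitosis and G2/M genes lay above 0 (median 0.53) and 22 were higher over the list alone. BIRC5 was higher by 1.24 (SE 0.13), CCNB1 by 1.21 (SE 0.13), HMMR, which encodes a spindle-associated hyaluronan receptor, by 1.13 (SE 0.13) and CDC20 by 1.00 (SE 0.14). Of 18 tubulin genes 9 were higher over the list alone (median 0.48). They included TUBB8 at 1.11 (SE 0.17), TUBB6 at 0.89 (SE 0.15), TUBB3 at 0.78 (SE 0.13) and TUBA1C at 0.69 (SE 0.14). Interferon-induced genes had a median of 0.33, with 32 of 33 above 0, although no member passed over the list alone. Their leading values were 0.92 for HERC6 (SE 0.16), 0.71 for RIGI (SE 0.17), 0.61 for IFIT5 (SE 0.14) and 0.61 for OAS3 (SE 0.18). The preset camera test gave mitosis an adjusted p of 6.27e-19 and tubulins 2.3e-07 (adjusted p = 0.327 with an estimated correlation). Interferon genes had 6.62e-05, mesenchymal genes 0.000963 (median -0.34) and histones 0.0116 (median -0.22, which turned to 0.28 with median centring). These 3 lists each had adjusted p = 0.74 with an estimated correlation. The interferon median was 0.13 with ratio compression removed and the mesenchymal one -0.06, the latter no longer called. On slide 1, which holds an untreated and a treated Neo array, the medians were 0.55 for mitosis, 0.52 for tubulins, 0.45 for interferon, -0.44 for mesenchymal genes and -0.28 for histones.

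Limma called 1 of 20470 genes in Neo cells, PMF1, a kinetochore gene (log2 change -5.07, SE 0.14, adjusted p = 0.00635), and 1639 had an unadjusted p under 0.05. That call rests on a single spot of the untreated Neo array, where the local Cy3 background was 2801.5 units against 45 to 56 on the other arrays. Without background subtraction the PMF1 change was 0.17 (SE 0.14). The next genes did not pass, each at an adjusted p of 0.606. They were CABP4 (1.32, SE 0.14), BIRC5 and CCNB1 on the higher side, and PNRC1 (-1.02, SE 0.13) and the telomerase RNA gene TERC (-1.01, SE 0.13) on the lower. The count was 0 with slide as a block and without either Neo docetaxel array.

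In PAR4 cells after docetaxel, the median change was above 0 for tubulin and interferon-induced genes and below 0 for immediate early, hypoxia and stress-response genes, each called by the preset camera test. None of these 5 lists was called otherwise (adjusted p from 0.505 to 0.506 with an estimated correlation), and the interferon median of 0.21 with ratio compression removed was not called either. Limma called 998 of 20210 genes, 197 higher and 801 lower, and 547 of them by at least 2-fold. The excess of falls depends on the scaling. It turned to 451 higher and 318 lower with median centring and to 2677 higher and 2032 lower in the Cy5 channel alone. Those fits put the median of all genes at 0.08 and 0.119. Of 17 tubulin genes 6 rose and 1 fell over all genes (11 and 1 over the list alone, median 0.52). TUBB (0.95, SE 0.14), TUBA1A (0.90, SE 0.14) and the gamma-tubulin gene TUBG2 (0.84, SE 0.13) rose, while TUBB2B fell by 1.56 (SE 0.28). TUBB8 rose by 1.17 (SE 0.17) with its main probe and read -0.43 with another. Of 33 interferon-induced genes 4 rose over all genes, namely USP18 (1.42, SE 0.23), OAS1 (1.30, SE 0.23), OAS3 (1.05, SE 0.18) and IFI35 (0.87, SE 0.13). Over the list alone 9 were higher and 2 lower, BST2 (-0.66, SE 0.14) and MX2 (-0.72, SE 0.14, other probe 0.30), for a median of 0.49. Mitosis genes had a median of 0.11, which was 0.44 with ratio compression removed, with 4 that rose and 3 that fell over all genes (9 and 4 over the list alone). CDC20 (1.30, SE 0.14), AURKB (1.03, SE 0.13) and PLK1 (0.94, SE 0.14) rose. CENPF (-1.07, SE 0.16), CDK1 (-1.02, SE 0.13) and NUSAP1 (-0.75, SE 0.13) fell, and TOP2A at -0.61 (SE 0.15) was lower over the list alone.

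Of 25 immediate early genes 9 fell over all genes in PAR4 cells (14 lower and 3 higher over the list alone, median -0.66). Among them were EGR1 (-1.57, SE 0.13), EGR2 (-1.49, SE 0.13), FOS (-0.98, SE 0.13) and JUN (-0.85, SE 0.13). KLF4 (0.64, SE 0.13), IER3 (0.58, SE 0.14) and JUNB (0.39, SE 0.13) were higher over the list alone. Of 23 hypoxia and glycolysis genes 5 fell (10 over the list alone, median -0.40). ADM fell by 2.00 (SE 0.19), LDHA by 1.56 (SE 0.27), the hexokinase gene HK2 by 1.38 (SE 0.14) and the prolyl hydroxylase gene P4HA1 by 0.96 (SE 0.13). Among 29 genes of the integrated stress and unfolded protein responses 6 fell and 1 rose (10 and 3 over the list alone, median -0.31). HSP90B1 (-1.55, SE 0.22), ATF4 (-1.24, SE 0.18) and HERPUD1 (-1.13, SE 0.15) fell and XBP1 rose by 1.69 (SE 0.19). SLC3A2 (1.23, SE 0.31) and ATF5 (0.63, SE 0.13) were higher over the list alone.

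Of 32 DNA replication genes 4 fell over all genes in PAR4 cells (9 over the list alone), namely PCNA (-1.29, SE 0.13), MCM3 (-1.06, SE 0.14), TYMS (-1.01, SE 0.15) and RFC4 (-0.95, SE 0.13). The replication median was -0.24. With median centring it was 0.01, below the median of all genes at 0.08, and the list was not called. With ratio compression removed camera pointed the other way and TYMS read 0.05. Of 30 ribosomal protein genes 6 fell (9 lower and 1 higher over the list alone), with a median of -0.51 that turned to 0.49 with median centring. RPL5 fell by 2.34 (SE 0.29), RPL23 by 1.94 (SE 0.22), RPL7 by 1.92 (SE 0.23) and RPS24 by 1.78 (SE 0.20), while RPL18 read 0.59 (SE 0.15) and was higher over the list alone. The preset camera test gave adjusted p = 5.79e-05 for tubulins and 0.000176 for interferon, immediate early and hypoxia genes alike. It gave 0.00947 for stress genes, 0.00998 for replication, 0.0303 for mitosis and 0.0411 for ribosomal genes. None of these 8 lists was called otherwise (adjusted p from 0.505 to 0.737 with an estimated correlation).

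The largest rises in PAR4 cells were CDH1, which encodes E-cadherin (2.79, SE 0.33, limma adjusted p = 0.0404), TTC39A (2.21), XBP1, the small nucleolar RNA gene SNORA62 (1.60), TUBB4B (1.60) and FAM83H (1.56). USP18, OAS1, CDC20 and IDH2 (1.28) followed. In the Cy5 channel alone CDH1 read -0.53, XBP1 -0.16 and FAM83H -0.06, opposite to their ratios. The largest falls were VIM, which encodes the mesenchymal filament vimentin (-4.70, SE 0.82, limma adjusted p = 0.0483), and the liver genes ALB (-4.55), AFP (-4.28) and APOH (-3.49). LDHB (-4.17), PTX3 (-3.61), ANXA1 (-3.34), ARHGDIB (-3.30), IGFBP1 (-3.20) and CDK6 (-3.11) fell as well. Beside these rises and falls stands a property of the untreated PAR4 array, whose log ratios lay closer to 0 (SD over genes 0.75, against 0.85 to 1.12 on the others). ALB read -2.40 there and -6.96 to -5.54 on the other arrays. The melanocyte gene TYR read -1.50 against -4.12 to -2.91, and the erythroid gene HBG1 -0.97 against -4.14 to -2.00.

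The luminal list had a median of 0.65 in PAR4 cells (adjusted p = 0.00314, and adjusted p = 0.737 with an estimated correlation). The mesenchymal list had -0.34, but 0.05 without the first PAR4 docetaxel array (adjusted p = 0.043, and adjusted p = 0.737 with an estimated correlation). Reference genes had a median of -0.32 that turned to 0.62 with median centring (adjusted p = 0.00947, and adjusted p = 0.653 with an estimated correlation). The PAR4 median of tubulins was 0.71 with ratio compression removed, that of immediate early genes -0.46, of stress genes -0.25 and of hypoxia -0.20. Those of luminal (0.14), mesenchymal (-0.12), reference (-0.11) and ribosomal genes (-0.08) were then no longer called. On slide 2, which holds an untreated and a treated PAR4 array, the medians were 0.57 for tubulins, 0.56 for interferon, 0.07 for mitosis, -0.54 for immediate early genes and -0.47 for hypoxia. They were -0.25 for stress genes, -0.29 for replication, -0.31 for ribosomal, 0.45 for luminal and -0.75 for mesenchymal genes.

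**Figure D2:**
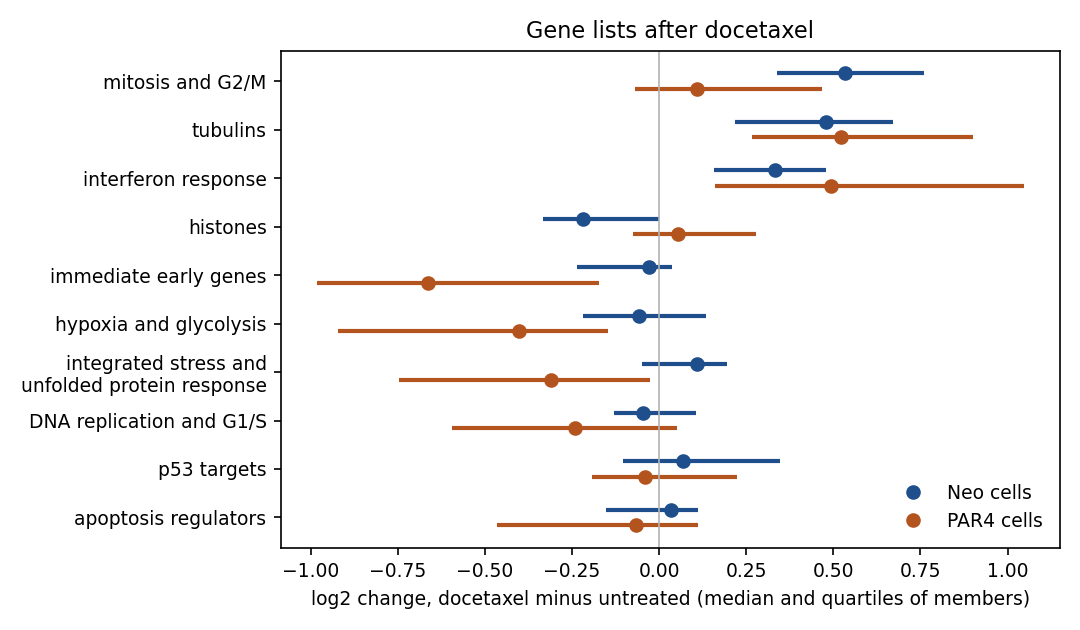
Log2 change after docetaxel (x axis) of 10 gene lists (y axis) in Neo cells, 2 arrays against 1, and in PAR4 cells, 2 arrays against 1; points are medians over the measured members and bars their quartiles. The mitosis median is 0.53 in Neo and 0.11 in PAR4 cells, and the immediate early median -0.03 in Neo and -0.66 in PAR4 cells.

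**Figure D3:**
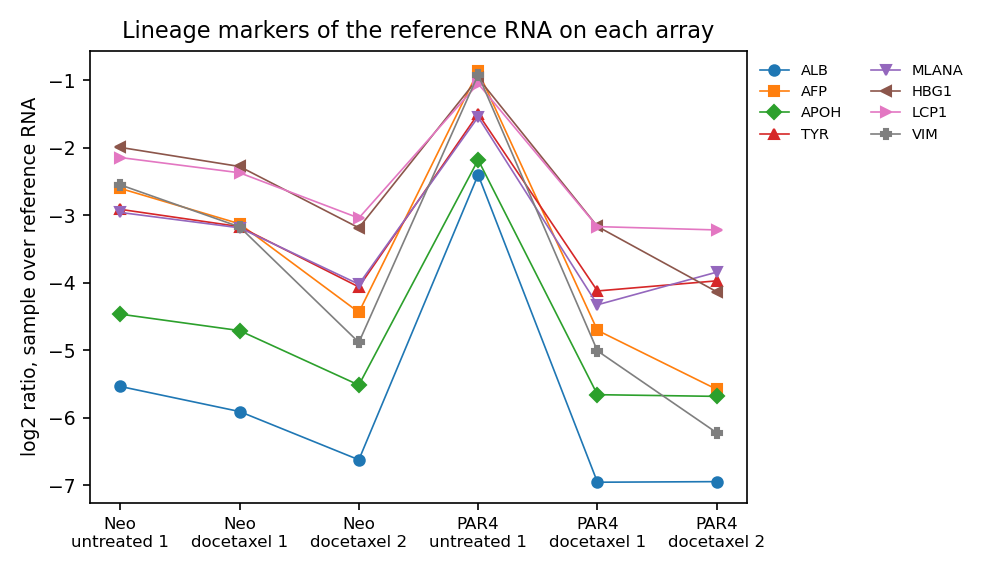
Log2 ratio over the reference RNA (y axis) of 8 lineage genes on each of the 6 arrays (x axis); each symbol is a gene and lines only join its values. All 8 genes are highest on the untreated PAR4 array, where ALB reads -2.40.

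The count of 998 genes in PAR4 cells fell to 0 with slide as a block (4374 at an unadjusted p under 0.05, against 5119), a normexp offset of 16, Agilent's processed signals, the deposited values, an intensity trend, ratio compression removed, or either Neo docetaxel array left out. That count was 4780 without background subtraction, 4709 in the Cy5 channel alone and 2571 with both channels above background on all arrays. P4HA1 (0.22) and ATF4 (0.69) too were opposite to their ratios in the Cy5 channel alone. In simulated data with 200 of 20184 genes changed, 0% of changes of 1 and 89.5% of changes of 2 on the log2 scale were recovered for this comparison. These shares need not hold here, where 5119 genes had an unadjusted p under 0.05 and only 547 of the 998 called changed at least 2-fold.

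Whether PAR4 changed the response to docetaxel was tested as the difference between the changes in PAR4 and in Neo cells. Among the lists called by the preset camera test, the median difference was below 0 for mitosis (-0.42 over 31 genes), immediate early (-0.61), hypoxia and glycolysis (-0.31) and stress-response genes (-0.34). None of these 4 was called otherwise (adjusted p = 0.577 with an estimated correlation), and 0 members passed over all genes by limma. With ratio compression removed the medians were -0.12 for mitosis and -0.14 for hypoxia, no longer called, and -0.34 for immediate early and -0.28 for stress genes, still called. Over the mitosis list alone 6 genes differed downward, among them CENPF (-1.87, SE 0.23), CDK1 (-1.37, SE 0.18), HMMR (-1.33, SE 0.18) and NUSAP1 (-1.04, SE 0.18). AURKB alone differed upward (0.84, SE 0.18). EGR2 (-1.76, SE 0.19), EGR1 (-1.46, SE 0.19), JUN (-1.16, SE 0.18) and DUSP1 (-1.08, SE 0.19) led the 9 immediate early genes that differed over their list. HK2 (-1.61, SE 0.19), ADM (-1.62, SE 0.27), P4HA1 (-1.29, SE 0.19) and the mitophagy gene BNIP3 (-0.96, SE 0.20) led the 5 of hypoxia. The preset camera test gave adjusted p = 0.00125 for mitosis and hypoxia and 0.00412 for immediate early and stress genes.

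Histone genes (median difference 0.33, adjusted p = 0.0114) and reference genes (-0.50, adjusted p = 0.00412) were called for this difference with the preset value, both at adjusted p = 0.691 with an estimated correlation. Luminal genes (0.43, adjusted p = 0.0156) and ribosomal genes (-0.38, adjusted p = 0.0101) were called in the same way, both at adjusted p = 0.793 with an estimated correlation, and the ribosomal median turned to 0.08 with median centring. With ratio compression removed none of these last 4 lists was called (medians 0.16 for histones, -0.15 for reference, 0.14 for luminal and -0.05 for ribosomal genes). Tubulins, with a median difference of 0.05 and a mean of -0.01, and interferon genes, with a median of 0.24, were not called (adjusted p = 0.465 and 0.203). Limma called 1 of 20202 genes for this difference, PMF1 (5.45, SE 0.20, adjusted p = 0.0249), whose untreated Neo spot has the raised local background given above, and 3028 had an unadjusted p under 0.05. The next genes did not pass. MAF1 (1.37, SE 0.20), ODF2L (-3.08, SE 0.25), EIF3E (-2.30, SE 0.21) and the proteasome gene PSMA4 (-2.00, SE 0.19) had an adjusted p of 0.166, and TNNC1 (1.34, SE 0.20) one of 0.168. All of these differences include both unreplicated untreated arrays, and the count was 0 with slide as a block and 968 without background subtraction. Across genes, which are not independent replicates, the docetaxel changes of the lines, which share no array, had a Pearson r of 0.32 and the same sign for 60.9% of 20202 genes.

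The comparison replicated on both sides sets docetaxel-treated PAR4 cells against docetaxel-treated Neo cells, 2 arrays each. By the preset camera test PAR4 cells had lower levels of stress-response, interferon-induced, immediate early and hypoxia genes and higher levels of histone and tubulin genes as groups. None of these 6 lists was called otherwise (adjusted p from 0.653 to 0.697 with an estimated correlation). Limma called 1771 of 20496 genes, 677 higher and 1094 lower in PAR4 cells, and 269 of them by at least 2-fold. The largest differences downward were HLA-C (-2.10, SE 0.21, limma adjusted p = 0.0303) and HLA-B (-1.91, SE 0.22), which encode class I antigen-presenting molecules. Then came SLITRK4 (-1.87), the antisense RNA gene KCNQ1OT1 (-1.77), the gastrin-releasing peptide receptor gene GRPR (-1.76), AGR2 (-1.75), ABCA5 (-1.74), PODXL (-1.60) and P4HA1 (-1.60, SE 0.11). SLITRK4 was not well above background on 1 of the 6 arrays, so its size and rank are less sure. SLC1A6 also passed downward (limma adjusted p = 0.0303) but was not well above background on either PAR4 docetaxel array, so that its size and rank are not given. The largest differences upward were SNORA23 (1.92, SE 0.15, limma adjusted p = 0.0303), SCARNA1 (1.73), SNORD15A (1.70), SNAR-A3 (1.66) and RMRP, the RNA of the mitochondrial RNA processing ribonuclease (1.50). The histone genes H4C3 (1.49) and H4C13 (1.43), PCDH10 (1.46), SNORA62 (1.45) and SNORA2A (1.44) followed. Signals of the small RNA and histone genes may also depend on how the RNA was labelled, which was not tested. Another probe of HLA-B read 0.12. The HLA, histone, tubulin and SNAR genes belong to families of near-identical copies that a 60-base probe can fail to separate.

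**Figure D4:**
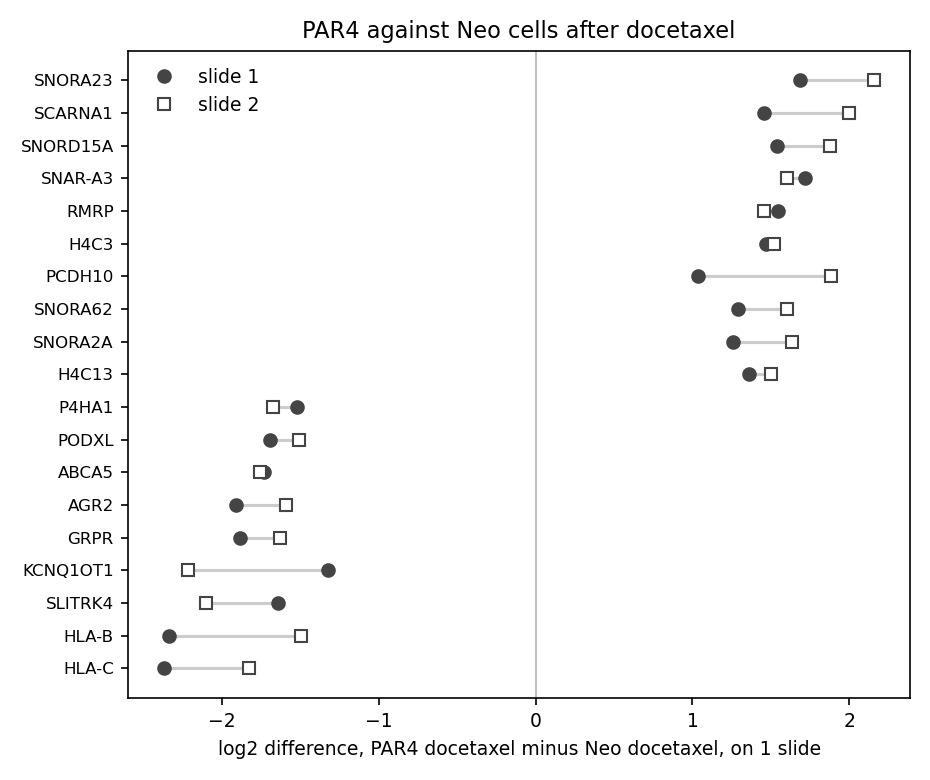
Log2 difference between docetaxel-treated PAR4 and Neo cells (x axis) for the 10 called genes with the largest rise and the 10 with the largest fall (y axis) except SLC1A6, which was not well above background in docetaxel-treated PAR4 cells, separately on slide 1 (filled circles) and slide 2 (open squares), 1 array per line on each slide. The same sign on both slides follows from the choice of genes, whose arrays had to lie apart between the lines, and is no separate evidence. HLA-C is the lowest in the mean, at -2.10.

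Stress-response genes showed the list result of smallest p in docetaxel-treated cells. Of 29 genes of the integrated stress and unfolded protein responses, 10 were lower in PAR4 cells over all genes (15 lower and 2 higher over the list alone, median -0.41). They included the cystine transporter gene SLC7A11 (-1.45, SE 0.11), PDIA4 (-1.19, SE 0.13), STC2 (-1.19, SE 0.12) and HERPUD1 (-0.91, SE 0.12). PHGDH (0.50, SE 0.10) and SLC3A2 (0.76, SE 0.25, and -0.14 in the Cy5 channel alone) were higher over the list alone. Of 33 interferon-induced genes 9 were lower over all genes (14 lower and 1 higher over the list alone, median -0.31). Among them were XAF1 (-1.50, SE 0.14), BST2, which encodes tetherin (-1.46, SE 0.11), IFIT2 (-1.31, SE 0.14) and IFI44 (-1.25, SE 0.12), with IFI35 at 0.46 (SE 0.11). Of 25 immediate early genes 7 were lower (14 lower and 3 higher over the list alone, median -0.49). EGR2 (-1.38, SE 0.11), EGR1 (-1.20, SE 0.11), DUSP1 (-0.998, SE 0.11) and JUN (-0.69, SE 0.10) led them, and JUNB (0.49), IER3 (0.51) and DUSP5 (0.34) were higher over the list alone.

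Of 23 hypoxia and glycolysis genes 5 were lower and 1 higher after docetaxel in PAR4 cells (9 and 2 over the list alone, median -0.33). P4HA1, HK2 (-1.21, SE 0.11), P4HA2 (-0.75, SE 0.11, other probe 0.16) and VEGFA (-0.64, SE 0.10) were lower. The glycolytic enzyme gene ENO1 was higher (0.63, SE 0.12), and ALDOA was higher over the list alone (0.43, SE 0.11). Estrogen-response genes had a median of -0.26 over 32 genes and were called by the preset test only (adjusted p = 0.743 with an estimated correlation). With median centring the median was 0.06, below that of all genes at 0.165, and the preset test still called the list. STC2, NRIP1 (-1.12, SE 0.12), the chemokine gene CXCL12 (-0.95, SE 0.11) and TFF3 (-0.86, SE 0.11) were lower, and the cyclin D1 gene CCND1 was higher (0.55, SE 0.11). Over that list alone 10 were lower and 1 higher. Histone genes had a median of 0.36 over 16 genes, with 3 higher and 1 lower (7 and 1 over the list alone). These were H4C3, H3C4 (1.13, SE 0.12) and H4C5 (0.72, SE 0.13), and the linker histone gene H1-2 on the lower side (-0.70, SE 0.11), which read 0.04 in the Cy5 channel alone. Of 18 tubulin genes 3 were higher, TUBA1A (0.96, SE 0.11), TUBG2 (0.79, SE 0.11) and TUBB (0.64, SE 0.12), and TUBA8 was lower over the list alone (-0.52, SE 0.13), for a median of 0.25.

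By the preset camera test the adjusted p in docetaxel-treated cells was 2.24e-05 for stress genes and 0.00674 for interferon, immediate early and hypoxia genes alike. It was 0.00698 for histones and tubulins, and none of these 6 was called otherwise (adjusted p from 0.653 to 0.697 with an estimated correlation). Estrogen-response genes had 0.00674 (adjusted p = 0.743 with an estimated correlation). Reference genes (median -0.43) had 0.0268 (adjusted p = 0.743 with an estimated correlation) and mitosis genes (median -0.19) 0.0497 (adjusted p = 0.697 with an estimated correlation). With median centring the medians of these lists were 0.08 and 0.09, below that of all genes at 0.165, and neither list was called. Reference genes (-0.21) and mitosis genes (-0.09) were no longer called with ratio compression removed, while the other lists were, with the hypoxia median at -0.15 and the histone median at 0.30. On slides 1 and 2 separately the medians were -0.46 and -0.47 for stress genes, -0.36 and -0.25 for interferon, -0.44 and -0.53 for immediate early genes and -0.37 and -0.39 for hypoxia. They were -0.37 and -0.13 for estrogen response, 0.32 and 0.31 for histones and 0.20 and 0.23 for tubulins.

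With slide as a block, which leaves 1 residual degree of freedom, the count of 1771 in docetaxel-treated cells fell to 0 (smallest adjusted p 0.0705, 5295 genes at an unadjusted p under 0.05 against 5520). It was also 0 with a normexp offset of 16, with Agilent's processed signals and without either Neo docetaxel array, 306 in the Cy5 channel alone, and 1033 (913 higher and 120 lower) with median centring, which put the median of all genes at 0.17 in place of -0.03. In simulated data with 200 of 20184 genes changed, 0% of changes of 1 and 93% of changes of 2 on the log2 scale were recovered for this comparison. These shares need not hold here, where 5520 genes had an unadjusted p under 0.05 and only 269 of the 1771 called changed at least 2-fold.

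Untreated PAR4 and Neo cells were compared with 1 array each, on different slides. Interferon-induced genes were lower in PAR4 cells as a group by the preset camera test, with 31 of 33 below 0 and a median of -0.57. Neither this list nor the estrogen, luminal and heat shock lists was called otherwise (each adjusted p = 0.438 with an estimated correlation). IFIT2 (-1.29, SE 0.20) passed over the list alone, and IFIT3 (-0.95, SE 0.18), XAF1 (-0.84, SE 0.20, other probe 0.16) and CMPK2 (-0.79, SE 0.17, other probe 0.20) did not. Estrogen-response genes had a median of -0.28 over 31 genes. With median centring it was 0.08, still below the median of all genes at 0.287, and the preset test still called the list. XBP1 (-1.59, SE 0.21), CXCL12 (-0.93, SE 0.15) and ADCY9 (-0.93, SE 0.16) were lower over the list alone, and GREB1 read -1.01 (SE 0.26). All 18 luminal epithelial genes lay below 0 (median -0.52). CDH1 (-2.50, SE 0.38), EPCAM (-1.44, SE 0.25) and AGR2 (-1.39, SE 0.22) passed over the list alone, and ESR1 at -0.63 (SE 0.22, other probes 0.16) did not. Heat shock genes stood higher (median 0.19 over 19 genes), but at -0.07 in the Cy5 channel alone. The mitochondrial chaperonin gene HSPE1 (1.48, SE 0.20), HSP90AA1 (1.06, SE 0.25), HSPA8 (0.81, SE 0.21) and HSPH1 (0.59, SE 0.15) were among 5 higher over the list alone. The low luminal values stand beside the narrower range of ratios on the untreated PAR4 array given above, and in the Cy5 channel alone EPCAM read 0.31, GREB1 0.26 and HSPA8 -0.22.

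By the preset camera test on untreated cells the adjusted p was 4.16e-13 for interferon, 3e-09 for estrogen response, 1.39e-08 for luminal and 0.0481 for heat shock genes, and for each of the 4 adjusted p = 0.438 with an estimated correlation. Ribosomal genes (median 0.37) had 7.64e-07 and mitosis genes (0.24) 0.000744. Replication genes (0.11, but -0.03 with ratio compression removed) had 0.0455. Reference genes (0.22, but -0.04 with ratio compression removed), tubulins (0.18, but -0.13 in the Cy5 channel alone) and basal epithelial genes (-0.19) each had 0.0481. With median centring the basal median was 0.19, below that of all genes at 0.287, and the basal list was not called. None of these 6 lists was called otherwise (adjusted p from 0.438 to 0.54 with an estimated correlation). The medians were -0.34 for interferon with ratio compression removed, -0.23 for luminal and 0.10 for ribosomal genes, and heat shock (0.04), mitosis (0.08), tubulin (0.06), basal, replication and reference genes were no longer called.

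Limma called 1 of 20202 genes in untreated cells, PMF1 (-5.32, SE 0.17, adjusted p = 0.0101), on the spot described above, and 1686 had an unadjusted p under 0.05. With slide as a block limma called 0 (778 at an unadjusted p under 0.05, smallest adjusted p 0.178). The next genes did not pass, each at an adjusted p of 0.413. They were PAWR and the translation factor genes EIF1AX (1.48, SE 0.15) and EIF3E (1.69, SE 0.17) on the higher side, and SLITRK4 (-1.93, SE 0.24) and GRPR (-1.27, SE 0.16) on the lower. In simulated data with 200 of 20184 genes changed, 0.5% of changes of 1 and 82.5% of changes of 2 on the log2 scale were recovered, shares that need not hold for these data. Across genes, the PAR4 against Neo differences before and after docetaxel, which share no array, had a Pearson r of 0.09.

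Of the 25 lists, 10 were called by camera in none of the 6 comparisons. In docetaxel-treated PAR4 against Neo cells their medians were -0.06 for p53 targets (adjusted p = 0.55), -0.07 for apoptosis regulators (adjusted p = 0.986), 0.11 for known partners of PAWR (adjusted p = 0.475) and -0.14 for microtubule-associated proteins (adjusted p = 0.956). They were -0.08 for NF-kB and cytokine genes (adjusted p = 0.719), -0.22 for cholesterol synthesis (adjusted p = 0.0689), -0.09 for autophagy and lysosome (adjusted p = 0.596) and -0.06 for leukocyte markers (adjusted p = 0.986). Drug transport and metabolism genes had a median of 0.03 and a mean of -0.07 and endothelial markers a median of 0.04 and a mean of -0.07, with camera pointing down in both (adjusted p = 0.986). Single members did pass over all genes by limma in that comparison. They were 1 higher and 3 lower for p53 targets, 1 and 5 for apoptosis regulators, 2 and 1 for partners, 2 and 0 for microtubule-associated proteins and 1 and 2 for drug transport. For NF-kB they were 0 and 1, for cholesterol 1 and 5, for autophagy 0 and 3, for leukocytes 0 and 0, and for endothelium 0 and 1. The 2 members counted as higher for partners include PAWR, the transfected gene, which is itself on that list.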

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

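The tests on the untreated PAR4 array and on PMF1 were chosen after the result was seen. Removal of the GC trend and of ratio compression was added after the data were seen, but what each test would show for the genes called between the lines was written before its result. No group has more than 2 arrays, so no array was tested as lying far from its group.

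The results below were picked out because the test of the difference itself gave a different response to docetaxel in PAR4 and Neo cells. For single genes this was PMF1, at 5.451 on the log2 scale. For lists, by camera with the preset correlation, the median differences were -0.4244 for mitosis, 0.331 for histones, -0.611 for immediate early genes, -0.3401 for stress-response genes and -0.3091 for hypoxia. They were 0.4258 for luminal, -0.3845 for ribosomal and -0.5039 for reference genes. None of these 8 lists was called with an estimated correlation.

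With ratio compression removed, immediate early genes kept a median difference of -0.34 (adjusted p = 0.0352, range over 20 alternatives 2.69e-05 to 0.577) and stress-response genes one of -0.28 (adjusted p = 0.0129, range 0.000371 to 0.577), and both stayed called. Mitosis genes moved to -0.12 (adjusted p = 0.0522, range 2.69e-05 to 0.577) and hypoxia genes to -0.14 (adjusted p = 0.0649, range 8.64e-05 to 0.577), and neither stayed called. Histones moved to 0.16 (adjusted p = 0.235, range 0.000107 to 0.691), luminal genes to 0.14 (adjusted p = 0.944, range 0.000151 to 0.944), ribosomal genes to -0.05 (adjusted p = 0.8, range 0.000377 to 0.851) and reference genes to -0.15 (adjusted p = 0.695, range 0.000371 to 0.695), and none of these stayed called.

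PMF1 had a high ratio on the untreated Neo array, where the local Cy3 background read 2801.5 units against a Cy3 signal of 1994 units. Without background subtraction the docetaxel change in Neo cells was 0.1701 in place of -5.07. A raised background beside 1 spot is thus a candidate cause that the test left standing. PMF1 in Neo cells also read 0.1671 with processed signals, 0.5489 in the Cy5 channel alone and 0.2491 with the deposited values. Among these fits the change of -5.07 appeared only where that local Cy3 background was subtracted. The Cy5 signal of PMF1 was 2037.5 units on that array and 2138 to 5026 units on the others, and a biological difference was not tested.

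The log ratios of the untreated PAR4 array lay closer to 0 than on the other arrays. Bright genes were chosen by their mean ratio on the Neo docetaxel arrays, 647 low and 353 high against the reference. On the untreated PAR4 array the low genes read 0.97 and the high genes -0.36 relative to docetaxel-treated PAR4 cells. The same differences in Neo cells, 0.41 and -0.29, are no fair baseline, since the choice of genes on the Neo docetaxel arrays itself pushes them that way. Optical bleed of Cy3 would put the Cy5 signal of the negative control spots at 41.7 units, but it was 26 units (other arrays 29.4, SD 4.88). Expression of the low genes in PAR4 cells whatever the treatment is argued against by their median of -0.141 between the lines after docetaxel (439 of 647 below 0). That sign rests on slide 2, where the low genes had a median of -2.87 in PAR4 and -2.37 in Neo cells. On slide 1 the medians were -2.48 in PAR4 and -2.57 in Neo cells. Slide alone and position alone are argued against, since the low genes read higher than in docetaxel-treated PAR4 cells on the same slide by a median of 1.177 (quartiles 0.82 to 1.65) and higher than in untreated Neo cells at the same position by 0.5193 (0.18 to 0.83). Reference RNA in the labelled sample, at a share of 17.1%, may account for the low genes and stays open, since the high genes went beyond its dilution by a median of -0.2264 with quartiles from -0.52 to 0.03 (genes beyond 2 on the log2 scale, a limit set after 2, 3 and 4 had been looked at, with quartiles of -0.57 to 0.09 over 42 high genes at 3 and -1.86 to -0.82 over 3 at 4). An effect of docetaxel on these genes in PAR4 cells and a part played by position stay open too, with 1 array of untreated PAR4 cells.

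The 1771 genes called between the lines after docetaxel were set against properties of probes and arrays. After removal of the trend with probe GC content 57.93% were still called with the same sign, and after removal of ratio compression 96.05%, which argues against either trend as the whole cause. Position on the slide goes with the line on both slides and was not separable by any array. PAR4 overexpression and other differences between the transfected lines stay open and were not told apart by a test.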

How the results depend on the processing

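Ratio compression removed and the GC trend removed were tests chosen after the data were seen, and the other alternatives were planned. Over all alternatives, the named genes had the same direction and the same side of the threshold in 3567 values, lost the call in 892 and gained it in 246. They reversed in 23 and moved within 1 slide in 2, HSP90B1 (-1.326) and SLC3A2 (0.8884), both after docetaxel in PAR4 cells. For the called lists 827 values stayed on the same side, 228 lost the call and 8 reversed. All 51 calls of lists were lost with an estimated correlation. Of the counts, 73 moved and 71 stayed within 1.5 times the count reported, 54 of these at 0 or 1 in both fits. Unless stated, the cause was not tested.

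Counts follow in the order mean of both lines, Neo cells, PAR4 cells, difference between lines, PAR4 against Neo after docetaxel, and PAR4 against Neo untreated. They were 0, 1, 998, 1, 1771 and 1, and without background subtraction 2813, 0, 4780, 968, 4782 and 0. Agilent's processed signals gave 0 in all 6, and the deposited values gave 2181 genes between the lines after docetaxel and 0 in the others. A normexp offset of 16 gave 0 in PAR4 cells and between the lines after docetaxel. Slide as a block and the replicate number as a block each gave 0 in all 6. Median centring gave 1256, 24, 769, 101, 1033 and 183 and put the median of all genes at 0.112, 0.18, 0.08, -0.07, 0.165 and 0.287, in place of 0.00983, 0.0363, -0.0128, -0.0529, -0.0338 and 0.0218. The Cy5 channel alone gave 2435, 0, 4709, 0, 306 and 7, with the median of all genes at 0.119 in PAR4 cells. The processed signals moved that median to -0.101 for untreated cells.

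Filters change the number of genes tested. Cy5 above background on all arrays gave 1 gene for the mean of both lines, 1900 in PAR4 cells and 2911 between the lines after docetaxel, and both channels above background gave 1127, 2571 and 3325. No filter, the mean of a gene's probes and every probe on its own each gave 1 gene for the mean of both lines, and the mean of probes 543 in PAR4 cells. An intensity trend gave 1 for the mean of both lines and 0 in PAR4 cells. A change of at least 2-fold left 547 in PAR4 cells and 269 between the lines after docetaxel. With ratio compression removed the mean of both lines had 1 gene, PAR4 cells 0 and the lines after docetaxel 4234, and with the GC trend removed 1, 553 and 1088. Of the 1771 genes, 1701 were shared with the former and 1026 with the latter.

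Aquantile between arrays changes no ratio, and the fit on the docetaxel arrays alone leaves the same residuals, so both repeat the counts by construction. Slide as a random block could not be fitted. Where limma gave 0, genes at an unadjusted p under 0.05 numbered 2332 to 6841, 362 to 2786, 3661 to 8375, 1365 to 5070, 3037 to 6261 and 778 to 3647 in the same order.

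Leaving out 1 array at a time, with a lone array assumed to vary like the other groups, gave 0 to 2903 genes for the mean of both lines, 0 to 2857 in PAR4 cells and 0 to 2796 between the lines after docetaxel. In the other comparisons it gave 0 to 1. Without the first or second PAR4 docetaxel array the mean of both lines had 957 or 2903 genes, PAR4 cells 2078 or 2857 and the lines after docetaxel 2796 or 2396. Without either Neo docetaxel array all 6 counts were 0. With 1 array left out the spread rests on the 2 arrays of the other docetaxel group, and the Neo docetaxel arrays correlated at r 0.98 and the PAR4 docetaxel arrays at r 0.961 over 20184 genes. The difference between replicates 1 and 2 had an r of 0.029 across genes between the docetaxel groups, which share the slide and the replicate number.

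Some directions reversed. PMF1 for the mean of both lines was 0.2707 without background subtraction, 0.3521 with processed signals, 0.5023 in Cy5 alone and 0.4069 with deposited values. In Neo cells it was 0.1701, 0.1671, 0.5489 and 0.2491 in the same order, and in Cy5 alone -0.09314 for the difference between lines and 0.3944 in untreated cells. A raised background beside 1 spot of the untreated Neo array was tested for PMF1 and is weighed separately. CDK1 for the mean of both lines was 0.06815 with median centring and 0.1971 with compression removed, and TYMS in PAR4 cells 0.04805 with compression removed. In Cy5 alone ATF4 was 0.6934, CDH1 -0.5251, FAM83H -0.06253, P4HA1 0.2181 and XBP1 -0.1611 in PAR4 cells. H1-2 was 0.03597 and SLC3A2 -0.1382 between the lines after docetaxel, and EPCAM was 0.3124, GREB1 0.2618 and HSPA8 -0.2158 in untreated cells. With median centring the replication list was 0.1731 for the mean of both lines, histones 0.2809 in Neo cells, and reference genes 0.6179 and ribosomal genes 0.4937 in PAR4 cells. Ribosomal genes were 0.07865 for the difference between lines. Luminal genes were 0.02509 for the mean of both lines in Cy5 alone. With compression removed camera turned for replication in PAR4 cells (-0.03074) and for reference genes in untreated cells (-0.04474).

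Signal over background limits which genes can be tested, since 65.2% to 73% of the spots were well above background in Cy3 and 72.3% to 78.1% in Cy5.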

Other observations

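The sets in this part were chosen after the values were seen, and so were the tests on them. Among 48 measured small nucleolar and Cajal body RNAs, 36 lay above 0 in docetaxel-treated PAR4 against Neo cells (median 0.34), and 15 were higher and 0 lower over all genes by limma. On slides 1 and 2 the medians were 0.38 and 0.44. Camera gave p = 1.12e-08 with the preset and p = 0.179 with an estimated correlation, without adjustment. SNORA23 (1.92), SNORA62 (1.45), SCARNA16 (1.40), SNORA81 (1.37), SCARNA12 (1.29), SNORA73B (1.04) and SNORA12 (1.01) were among the higher ones. The median was 0.37 with ratio compression removed, 0.45 with the GC trend removed, 0.76 in the Cy5 channel alone, 0.37 without background subtraction and 0.67 with median centring. In untreated cells 37 of 47 lay above 0 (median 0.19). These RNAs are short and mostly without a poly-A tail, so that their signal also depends on the host transcripts and on labelling, which was not tested.

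Among 16 genes of class I antigen presentation, 15 lay at or below 0 after docetaxel in PAR4 against Neo cells, with a median of -0.43 and 7 lower over all genes by limma. On slides 1 and 2 the medians were -0.42 and -0.58. Camera gave p = 1.56e-06 with the preset and p = 0.105 with an estimated correlation. TAP2 (-0.96), HLA-G (-0.91), ERAP1 (-0.89), B2M (-0.87) and HLA-A (-0.79, SE 0.14, limma adjusted p = 0.0372) passed, and PSMB8 (-0.49, limma adjusted p = 0.0589) and TAPBP (0.04) did not. The median was -0.38 with ratio compression removed, -0.50 with the GC trend removed, -0.66 in the Cy5 channel alone, -0.58 without background subtraction and -0.23 with median centring. In untreated cells the median was -0.28 (p = 2.23e-05 with the preset, p = 0.129 with an estimated correlation). HLA genes have near-identical copies, and another probe of HLA-B read 0.12.

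The 8 lineage markers of the reference RNA, among them ALB, VIM and TYR, had a median change after docetaxel of -3.09 in PAR4 cells, where 7 were lower over all genes, and -0.72 in Neo cells. In untreated PAR4 against Neo cells all 8 lay above 0 (median 1.52), and after docetaxel the median was -0.62, with none called by limma. Of 200 pairs of a named gene and a comparison, 59 have another tested probe, and 9 of these had the opposite sign, 3 of them beyond 0.25.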
